A study of Mus musculus with 12 samples.

How the data were processed

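Skin was taken from 12 diabetic mice in 3 groups of 4 on day 3 after full-thickness punch wounds were made in the back, and its RNA was sequenced. Per the labels' protocols, frozen tissue was pulverized, RNA was extracted with phenol and chloroform and treated with DNase, and stranded total-RNA libraries were made after removal of ribosomal RNA. Per the series design text there were 4 mice per group, so each library is read as 1 mouse and the spread within a group includes differences between animals.

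The deposited table held estimated counts per gene for the 12 libraries, as produced by the authors with kallisto 0.48.0 per the submitters' processing notes. Those notes also name FastQC 0.12.1, R 4.1.3, DESeq2 1.34.0 and the mouse genome build GRCm39, without giving the role of each. The values were fractional and summed to different totals per library, as unnormalized estimated counts do. Kallisto assigns reads to transcripts by compatibility and divides shared reads between similar transcripts, so values of close paralogs (keratin 6, small proline-rich, late cornified envelope, haemoglobin, defensin and histone genes among them) are uncertain. How transcript values were summed to genes, and whether strand was used, is not given in the sources used here. The reference annotation at hand was of another build, GRCm38, so no coordinates are printed; 28187 of 29956 gene symbols matched its names.

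The table had 29957 entries, of which 1 had no gene name and was left out of totals and tests; it took 0.00909% to 0.0151% of each library. No gene name occurred more than once. Estimated counts were rounded to whole numbers before testing. Libraries held 38.4 to 71.3 M (mega) estimated counts. Replicates within a group were compared by a chi-square statistic of their counts over genes. It was 28.8 to 481 per degree of freedom, so no pair within a group looked like 1 library deposited under 2 names. Pairs across groups were not compared this way.

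Differences between groups were tested with edgeR 4.0.16 in R 4.3.3. All 12 libraries entered one model with a mean per group and no other term. Library sizes were scaled by TMM (trimmed mean of M-values), genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), and 18218 genes remained. The robust quasi-likelihood test was two-sided, and a gene was called when its Benjamini-Hochberg adjusted p over all genes tested was under 0.05. Levels are CPM, the counts per M (mega) of TMM-scaled library size, given as mean ± SD of 4 libraries. A log2 fold change is followed by its standard error (SE). For genes with about 0 counts in a group, summed counts are given with the ratio of the groups, scaled by their summed TMM-scaled library sizes, and its exact 95% interval, which covers counting error only.

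The 34 gene lists covered proteases and wound processes, cell types that skin and wound tissue could hold, and tissue quality. They were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, adjusted over the 34 lists, and again with a correlation estimated for each list. Camera compares a list with all other genes. The rotation test fry asks instead whether the members of a list move, on balance, one way. Of the 707 list symbols, 702 were found in the table, 13 of them under an older name; adhesion receptor E1, for example, stands as Emr1 and cellular communication network factor 1 as Cyr61. Some genes stand in more than one list, such as Plaur, Mmp8, Mmp9, S100a8 and Camp. A list score of a library is the mean log2 CPM of the members after subtracting each gene's mean over the 12 libraries.

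The groups, main test, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, for each comparison, the 8 called genes with the largest and the 8 with the smallest log2 fold change among those with a mean of at least 1 CPM and groups that did not overlap, up to 3 called members of each list by smallest adjusted p, and the metalloproteinases and their inhibitors, called or not. Predicted genes without a standard symbol were counted and not named, and the text gives in full only part of what the rule named. Genes named outside the rule are members of the lists, given with their values whether called or not, or are said to be chosen after their values were seen. Of the 28 wound-edge keratinocyte genes, 1 is not reported here by itself and is left out of the plot of that list; the list tests include it.

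The alternatives were DESeq2 size factors or upper-quartile scaling in place of TMM, DESeq2 1.42.0 (Wald test) or limma-voom in place of edgeR, no filter on low counts or a mean of at least 1 CPM, a fit of only the 2 groups compared, a minimum change of 2-fold, a threshold of 0.1, the replicate number as a block, and each of the 12 libraries left out in turn. After the data were seen, fits with a basal keratinocyte, adipocyte or neutrophil list score as a covariate, and fits on libraries thinned to the shallowest, were added.

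The edgeR procedure was tested on simulated data drawn from the real means and library sizes with 200 genes changed. The changed genes all had a mean of at least 1 CPM, and the noise was independent between genes. So many true changes also ease the adjusted threshold, so recovery in the real A. faecalis comparison may be lower. In the simulation of A. faecalis against vehicle, over 18028 genes, it recovered 23.9% of the genes changed 1.5-fold, 67.2% of those changed 2-fold and 93.9% of those changed 4-fold. In that of S. aureus against vehicle, over 18025 genes, it recovered 23.9%, 80.6% and 92.4%. Both comparisons against vehicle use the same 4 vehicle libraries. Their agreement was therefore compared with 20 simulations of unchanged groups and with the vehicle group divided 2 and 2. The simulations redrew every library, vehicle included, from a common mean per gene with independent noise, so they lack the structure of the real samples.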

Results

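Gene expression was measured by RNA sequencing in wounded skin of mice with the genotype B6.BKS(D)-Leprdb/db, which lack a working leptin receptor, become obese and diabetic, and are widely used to study slow wound closure. Wounds received Alcaligenes faecalis, a Gram-negative bacterium, Staphylococcus aureus, a Gram-positive skin pathogen, or a vehicle of buffered saline with glycerol, and skin was collected on day 3, with 4 mice per group. Library totals were 56.1 ± 4.58 M (mega) estimated counts (mean ± SD, n = 4) with vehicle, 57.3 ± 12 M with A. faecalis and 48.9 ± 9.62 M with S. aureus. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those for gene lists are from camera in limma. In a principal component analysis the first component took 32.8% of the variance. Vehicle replicate 3 lay at one end of it (-72.6) and the 4 S. aureus libraries at the other (23.3 to 60.0). The other vehicle and A. faecalis libraries lay between (-29 to 2.34).

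The first comparison asked what A. faecalis changed in the diabetic wound, with matrix metalloproteinase expression as the subject of the study's title. With A. faecalis, Mmp10 fell and Colq rose. Mmp10 encodes stromelysin-2, a matrix metalloproteinase made by keratinocytes at the wound edge. Its level was 2.40 ± 0.157 CPM (mean ± SD, n = 4) with A. faecalis and 9.35 ± 1.96 CPM with vehicle, a log2 fold change of -1.96 (SE 0.165, adjusted p = 0.000994 by edgeR). Colq encodes the collagen-like tail that anchors acetylcholinesterase at the neuromuscular junction. It was at 8.76 ± 1.40 CPM with A. faecalis and 2.80 ± 0.343 CPM with vehicle, a log2 fold change of 1.65 (SE 0.166, adjusted p = 0.0038 by edgeR). The levels of both genes in every A. faecalis library lay outside the range of the vehicle libraries. No other gene among 18218 passed the edgeR test, with 1399 genes at an unadjusted p under 0.05. Limma-voom also called 2 genes and DESeq2 called 121, of which 80 were lower with A. faecalis; the edgeR count was 10 without vehicle replicate 2 and 7 without vehicle replicate 4. The groups did not overlap in 738 genes, 4.05% of those tested, where chance gives 2.86%.

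Of the 21 matrix metalloproteinases measured, Mmp10 alone fell with A. faecalis at the threshold over all genes, and 4 were lower when adjusted over the list alone (Mmp10, Mmp12, Mmp13 and Mmp1b). Mmp13, collagenase-3, was at 15.4 ± 5.36 CPM with A. faecalis and 69.8 ± 33.4 CPM with vehicle, a log2 fold change of -2.18 (SE 0.376) with an adjusted p of 0.16 by edgeR. Mmp12, macrophage elastase, was at 22.2 ± 3.24 CPM against 54.9 ± 27.4 CPM (log2 fold change -1.30, adjusted p = 0.371). DESeq2 called Mmp10, Mmp12 and Mmp13. Mmp3, stromelysin-1, was at 153 ± 18.1 CPM against 213 ± 95.7 CPM (log2 fold change -0.48, adjusted p = 0.696). The abundant Mmp2, Mmp9, Mmp14 and Mmp19 had log2 fold changes of -0.13, 0.46, 0.28 and -0.05, and none was called. The list as a whole was lower by camera (adjusted p = 0.032, and 0.286 with an estimated correlation), and fry did not call it (adjusted p = 0.0738). Without vehicle replicates 1, 2 or 4 or A. faecalis replicates 1 or 2, the camera adjusted p was 0.0655, 0.0624, 0.0847, 0.0813 and 0.0569. Camera did not call the list with the replicate number as a block either. None of the 4 tissue inhibitors of metalloproteinases was called, and their list was not either (camera adjusted p = 0.268). The vehicle libraries were themselves uneven, vehicle replicate 3 being the lowest of them for Mmp3 and Mmp9 and the highest for Mmp12.

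**Figure D1:**
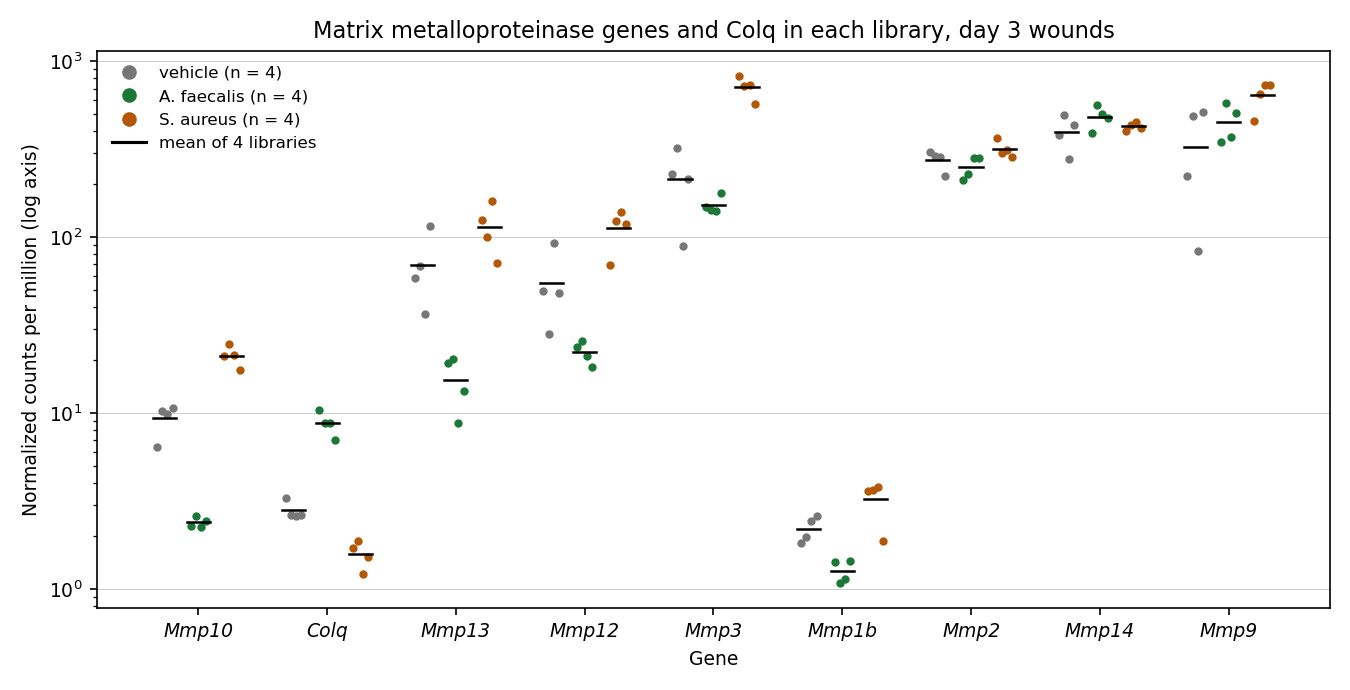
Normalized CPM (log axis) of 8 matrix metalloproteinase genes and Colq in the 12 libraries, each point 1 library and each bar the mean of 4. Mmp10 lies between 2.25 and 2.60 CPM with A. faecalis and between 17.6 and 24.8 CPM with S. aureus.

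Genes of the activated wound edge were lower with A. faecalis as a group. Of the 28 genes on the wound-edge keratinocyte list none was called over all genes by edgeR, while 13 were lower when adjusted over the list alone, among them Lama3, Gjb2, Gjb6, Itgb6, Tgfa, Hbegf, Areg, Krt16 and Krt17. The median log2 fold change of the list was -0.52, and it was lower by camera (adjusted p = 2.17e-12). It was the one list of this comparison whose call held with an estimated correlation (adjusted p = 0.0384), and the one that fry called (adjusted p = 0.00597). Lama3, a laminin chain of the epidermal basement membrane, had a log2 fold change of -1.60 (SE 0.25) with an adjusted p of 0.16. Gjb2, the gap junction protein connexin 26, was at 65.3 ± 12.2 CPM with A. faecalis and 156 ± 15.3 CPM with vehicle (log2 fold change -1.26, adjusted p = 0.172). The paralogs Krt6a and Krt6b, keratins of activated epidermis, had log2 fold changes of -0.99 and -1.03 (adjusted p = 0.498 and 0.467). Hbegf, a ligand of the epidermal growth factor receptor, was at 9.56 ± 0.939 CPM against 17.8 ± 2.44 CPM (log2 fold change -0.90, adjusted p = 0.16).

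Other epidermal lists were also lower with A. faecalis, without a called member. They were the basal keratinocyte list (13 genes, 6 lower when adjusted over the list alone; camera adjusted p = 2.27e-05, and adjusted p = 0.289 with an estimated correlation), the differentiated epidermis list (31 genes, 1 lower list alone; adjusted p = 1.02e-08 and 0.457) and the hair follicle list (12 genes, 1 lower list alone; adjusted p = 0.00139 and 0.241). The basal keratinocyte score was -0.191 ± 0.308 (SD, n = 4) with A. faecalis and 0.324 ± 0.202 with vehicle, so markers of keratinocytes in general moved with the wound-edge genes.

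**Figure D2:**
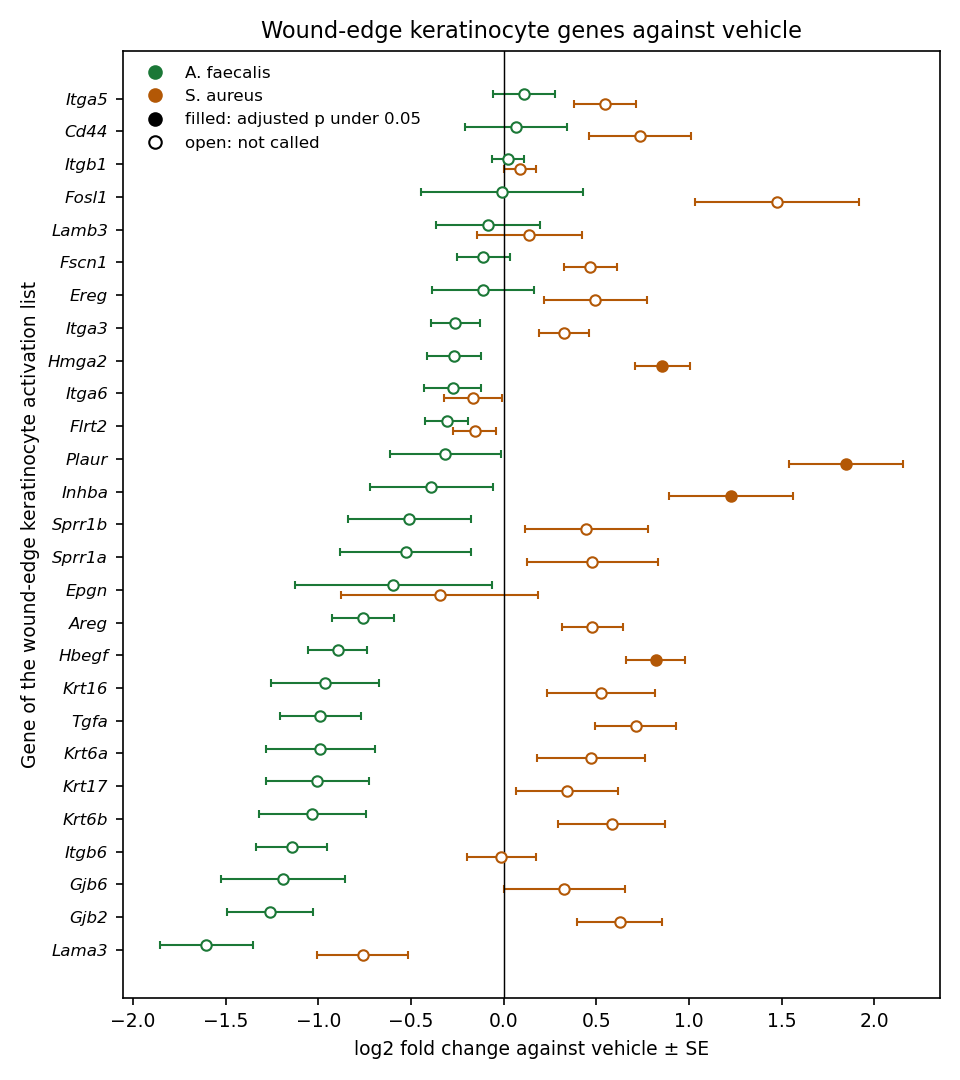
Log2 fold change against vehicle (± SE) of 27 wound-edge keratinocyte genes with A. faecalis (green) and S. aureus (orange), filled where called. With A. faecalis 24 of the 27 are below 0, and with S. aureus 22 are above 0.

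Immune lists moved in both directions with A. faecalis, again without a called gene. The pattern recognition list (28 genes; median log2 fold change 0.248, camera adjusted p = 1.6e-05) and the monocyte and macrophage list (19 genes; 0.276, adjusted p = 0.000753) were higher, with no gene called when adjusted over the list alone and adjusted p of 0.448 and 0.514 with an estimated correlation. The repair-associated macrophage list was lower (17 genes; median -0.466, camera adjusted p = 0.00231; adjusted p = 0.241 with an estimated correlation), with 6 genes lower when adjusted over the list alone. One of them was Cd209f, a lectin of tissue macrophages, at 9.91 ± 1.17 CPM with A. faecalis and 17.9 ± 3.08 CPM with vehicle (log2 fold change -0.86, adjusted p = 0.16). The neutrophil list passed camera as higher (adjusted p = 0.032; adjusted p = 0.798 with an estimated correlation) although its mean was -0.067 and its median 0.21, and without vehicle replicate 3 it leaned lower (adjusted p = 0.28). Its call was also lost without vehicle replicate 1, A. faecalis replicates 2 or 4 or S. aureus replicate 1 (adjusted p up to 0.402). The mast cell (13 genes, adjusted p = 0.000559), growth factor (28 genes, 3 lower when adjusted over the list alone, 0.00253) and erythroid (9 genes, 6 lower and 1 higher list alone, 0.00139) lists were lower, with adjusted p of 0.398, 0.241 and 0.398 with an estimated correlation. Vehicle replicate 3 had the highest adipocyte score of the 12 libraries (2.12, the other vehicle libraries -0.165 to 0.0149) and the lowest neutrophil score (-2.33, the others -1.25 to 0.631). It also had the lowest pattern recognition score (-0.736, the other vehicle libraries -0.343 to 0.231), which widened the difference of that list from A. faecalis. The pattern recognition list was still called without this library.

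Of the remaining lists, 4 were lower with A. faecalis, with no gene called when adjusted over the list alone, in calls that depended on single libraries. The skeletal muscle list (adjusted p = 0.00983, and 0.761 with an estimated correlation) lost its call without vehicle replicates 3 or 4 or A. faecalis replicate 2 (adjusted p up to 0.708), and the fibroblast list (0.0362 and 0.761) without vehicle replicates 1 or 3 or A. faecalis replicates 2 or 4 (up to 0.574). The interferon-stimulated list (0.00139, and 0.761 with an estimated correlation) lost it without vehicle replicate 3 or A. faecalis replicate 1 (up to 0.111), and the cell cycle list (0.00928 and 0.778) without vehicle replicate 1 or A. faecalis replicates 2 or 4 (up to 0.593). The other 18 lists were not called and held no called gene. Besides the inhibitors of metalloproteinases they were those of other wound proteases (camera adjusted p = 0.602), sebaceous gland (0.221), adipocytes (0.135), T and NK lymphocytes (0.0618), B and plasma cells (0.0875) and dendritic and Langerhans cells (0.602). Others were myofibroblasts and provisional matrix (0.268), endothelium (0.722), pericytes (0.602), Schwann cells (0.121), melanocytes (0.269) and cytokines (0.668). The last were IL-17 and antimicrobial response (0.556), complement and coagulation (0.0582), hypoxia and glycolysis (0.722), immediate-early genes (0.722) and mitochondrially encoded mRNA (0.121). When adjusted over the list alone, Cd4 was higher on the T and NK lymphocyte list, Oca2 on the melanocyte list and Defb4 lower on the IL-17 list, and 1 gene was higher and 3 lower on the dendritic cell list. Without vehicle replicate 3 the adipocyte list turned from lower to higher with A. faecalis, and the cytokine and hypoxia lists from higher to lower. All of them were called in that fit (0.00742, 0.0191 and 0.0394).

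Many of these calls and missing calls depended on 1 library. The adipocyte list was called lower without vehicle replicates 1, 2 or 4 or A. faecalis replicate 1 (camera adjusted p from 0.00375), and the T and NK lymphocyte list higher without vehicle replicate 2 or A. faecalis replicates 1, 3 or 4 (from 0.00534). The complement list was called without vehicle replicate 2, A. faecalis replicates 1 or 3 or S. aureus replicate 1 (from 0.0451), and the sebaceous gland list without vehicle replicate 2 or A. faecalis replicate 4 (from 0.0311). Leaving out vehicle replicate 3 or A. faecalis replicate 3 gave a call of the B and plasma cell list (from 0.0165), vehicle replicate 3 or A. faecalis replicate 1 of the myofibroblast list (from 0.000665), and vehicle replicate 2 or A. faecalis replicate 3 of the Schwann cell list (from 0.0128). The mitochondrial list was called without vehicle replicate 3 or A. faecalis replicate 4 (from 0.00306). The IL-17 and immediate-early lists were called lower with A. faecalis without vehicle replicate 3 (0.00306 and 0.0157). The hypoxia list was called higher without vehicle replicate 4 (0.00547), and the endothelial list was called without A. faecalis replicate 2 (0.0369).

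The second comparison gave the response to S. aureus against vehicle. Mmp10 rose to 21.2 ± 2.94 CPM from 9.35 ± 1.96 CPM (mean ± SD, n = 4; log2 fold change 1.18, SE 0.157, adjusted p = 0.00648 by edgeR), and Mmp3 rose to 715 ± 103 CPM from 213 ± 95.7 CPM (1.75, SE 0.295, adjusted p = 0.0107). Aldh1a2, a retinoic acid synthesizing enzyme, rose by a log2 fold change of 2.46 (SE 0.384, adjusted p = 0.00875). Krt15, a keratin of resting basal cells and hair follicle stem cells, fell by 4.23 on the log2 scale (SE 0.613, adjusted p = 0.00791; log2 fold change -3.52 without vehicle replicate 3) to 1.29 ± 0.687 CPM. EdgeR called 1246 genes, 705 higher and 541 lower, of which 218 and 206 changed at least 2-fold. Which direction held more genes depended on the scaling, with 619 higher and 679 lower under upper-quartile scaling and 774 and 489 under DESeq2 size factors, and on the threshold (1411 and 1448 at 0.1). In all, 4926 genes had an unadjusted p under 0.05. The groups did not overlap in 2757 genes, 15.1% of those tested against 2.86% by chance.

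The count of called genes with S. aureus depended on single libraries. It was 260 without S. aureus replicate 3, 381 without replicate 4, 451 without replicate 2, 672 without vehicle replicate 1 and 792 without A. faecalis replicate 3, and 350 when only the 2 groups were fitted. DESeq2 called 2851 genes and limma-voom 1278. Of the 79 called genes that the naming rule took, 22 were called in all 12 fits with 1 library left out, Mmp10, Mmp3, Aldh1a2 and Krt15 among them.

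Epidermal genes moved in both directions with S. aureus. On the wound-edge list 4 of 28 genes rose (Plaur, Hmga2, Hbegf and Inhba), of which Inhba lost its call without any 1 of 9 libraries, which were vehicle 1, 2 and 3, A. faecalis 1, 3 and 4, and S. aureus 2, 3 and 4 (adjusted p up to 0.132). On that list 11 genes were higher and 2 lower when adjusted over the list alone. The list was higher by camera (median log2 fold change 0.474, adjusted p = 0.000125; adjusted p = 0.398 with an estimated correlation). Plaur, the urokinase receptor, rose by a log2 fold change of 1.85 (SE 0.306, adjusted p = 0.0107), Hmga2, a chromatin protein, by 0.86 (SE 0.148, adjusted p = 0.0109), and Hbegf by 0.82 (SE 0.159, adjusted p = 0.0164; 0.0585 without S. aureus replicate 3). Krt77, a keratin of sweat ducts and interfollicular skin, fell to 4.09 ± 3.05 CPM from 68.6 ± 49.1 CPM (log2 fold change -4.07, adjusted p = 0.00875), and Flg2, a cornified envelope protein, fell by 2.99 on the log2 scale (SE 0.486, adjusted p = 0.01). Without vehicle replicate 3, which had the most of both, the log2 fold changes of Krt77 and Flg2 were -3.43 and -2.41. Tgm1, the cross-linking enzyme of the cornified envelope, rose by 1.53 (SE 0.308, adjusted p = 0.0193; 0.0605 without S. aureus replicate 3). The differentiated epidermis list thus had 2 genes higher and 2 lower, and it was not called (camera adjusted p = 0.64). The basal keratinocyte (adjusted p = 0.127) and hair follicle (0.598) lists were not called either, and the sebaceous gland list was lower with no gene called and 7 lower when adjusted over the list alone (0.000839; adjusted p = 0.398 with an estimated correlation).

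Of the matrix metalloproteinases, Mmp10, Mmp3 and Mmp15 rose and Mmp28 fell with S. aureus, and 4 were higher and 1 lower when adjusted over the list alone. The list was higher by camera (adjusted p = 0.00596; adjusted p = 0.398 with an estimated correlation). Mmp15, a membrane-type enzyme, rose by a log2 fold change of 0.59 (SE 0.129, adjusted p = 0.0241) and lost its call without S. aureus replicates 2, 3 or 4 (adjusted p up to 0.0724). Mmp28, epilysin, fell by 1.19 (SE 0.294, adjusted p = 0.0361; log2 fold change -0.74 without vehicle replicate 3), a call lost without 6 of the 12 libraries, which were vehicle 1, A. faecalis 3 and 4, and S. aureus 2, 3 and 4 (up to 0.115). Mmp12 was at 113 ± 29.9 CPM with S. aureus and 54.9 ± 27.4 CPM with vehicle (log2 fold change 1.04, adjusted p = 0.0642). Mmp8 and Mmp9, which neutrophils also carry, had log2 fold changes of 1.59 and 0.98 (adjusted p = 0.18 and 0.179). Timp4, an inhibitor also expressed in adipose tissue, fell by 2.64 (SE 0.647, adjusted p = 0.035). Its log2 fold change was -1.35 without vehicle replicate 3, which was at 161 CPM where the others were at 17.4 to 35.3. Its call was lost without A. faecalis replicate 3 or S. aureus replicates 2, 3 or 4 (up to 0.112). The inhibitor list was not called (0.279). Adamts4 and Adamts1, proteoglycan-cleaving proteases, rose by 1.54 (SE 0.265, adjusted p = 0.0109) and 0.61 (SE 0.116, adjusted p = 0.0159); with 4 genes higher and 1 lower, and 6 and 1 list alone, the list of other wound proteases was not called (0.145).

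Some inflammatory and antimicrobial genes rose with S. aureus. On the IL-17 and antimicrobial list 6 of 26 genes rose and 12 were higher when adjusted over the list alone (median log2 fold change 0.853, camera adjusted p = 1.03e-07; adjusted p = 0.398 with an estimated correlation). Il17a, an interleukin of T cells that induces antimicrobial proteins in keratinocytes, had 251 counts over the 4 S. aureus libraries, 26 over the vehicle libraries and 2 over the A. faecalis libraries. Scaled by library size, its level was 11.7 times as high with S. aureus as with vehicle (95% counting interval 7.8 to 18.3). Vehicle replicate 2 held 16 of the 26 vehicle counts, and without it the ratio was 23.5 (12.5 to 49.5). The call was lost without S. aureus replicate 3 (adjusted p = 0.0633). Against A. faecalis the vehicle level was 13.3 times as high (interval 3.34 to 116), and 6.65 times (1.42 to 62.5) without vehicle replicate 2. EdgeR did not call that difference. Il17ra, the receptor subunit, rose by a log2 fold change of 0.96 (SE 0.182, adjusted p = 0.0159), and Defb4, a beta-defensin with close paralogs, rose by 2.28 (SE 0.421, adjusted p = 0.0139) at a level of 4.08 ± 2.12 CPM. Cytokine genes rose in 5 of 32 cases and fell in 1, with 12 higher and 1 lower list alone (median 0.88, adjusted p = 5.01e-06, and 0.398 with an estimated correlation). Vehicle replicate 3 lowered the vehicle means of both lists. Its cytokine score was -1.47 (other vehicle libraries -0.676 to 0.374) and its IL-17 score -1.56 (-0.493 to 0.252). Both lists were still called by camera without that library. Il20, an epidermal cytokine, had 138 counts with S. aureus and 13 with vehicle, a ratio of 12.9 after scaling by library size (interval 7.28 to 24.8), and Ccl20, which draws CCR6-bearing cells, rose by 1.31 (SE 0.27, adjusted p = 0.0207). Osm, oncostatin M, rose by 2.28 (SE 0.438, adjusted p = 0.0162; 0.0505 without S. aureus replicate 3). Interferon-stimulated genes rose in 8 of 36 cases, and 14 were higher list alone (median 0.518, adjusted p = 1.03e-07, and 0.398 with an estimated correlation), with Gbp2, Oasl2 and Oas2 higher by 1.62, 1.11 and 0.64 (adjusted p = 0.014, 0.0134 and 0.0127).

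The neutrophil list had 2 of 25 genes called higher and 12 higher when adjusted over the list alone, and every member had a positive fitted change (median log2 fold change 1.24, camera adjusted p = 1.43e-09; adjusted p = 0.398 with an estimated correlation). The neutrophil score was 1.05 ± 0.293 (SD, n = 4) with S. aureus and -0.688 ± 1.36 with vehicle, so the vehicle libraries differed among themselves, replicate 3 being the lowest. S100a8, a calprotectin subunit of neutrophils and stressed keratinocytes, was at 4031 ± 679 CPM against 1418 ± 1080 CPM (log2 fold change 1.51, adjusted p = 0.113). Cd177 and Ceacam10, a neutrophil surface protein and a secreted member of the carcinoembryonic antigen family, rose by 2.49 (SE 0.526, adjusted p = 0.0228) and 2.77 (SE 0.593, adjusted p = 0.024). Chil5 and the glucose transporter Slc2a3 rose by 2.64 (adjusted p = 0.0241) and 2.60 (adjusted p = 0.0325). Without vehicle replicate 4 the changes of Ceacam10 and Slc2a3 were 3.36 and 3.42. Cd177 lost its call without S. aureus replicates 2 or 3 (adjusted p up to 0.0605), Ceacam10 and Chil5 without replicates 2, 3 or 4 (up to 0.0608 and 0.0703), and Slc2a3 without these or vehicle replicates 1 or 2 (up to 0.0919).

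Some macrophage genes fell with S. aureus. On the monocyte and macrophage list 3 of 19 genes fell, and 6 were lower and 1 higher when adjusted over the list alone (median log2 fold change -0.234, camera adjusted p = 0.0149; adjusted p = 0.55 with an estimated correlation); the list call was lost without vehicle replicate 2 or S. aureus replicate 2 (adjusted p up to 0.107). Emr1, which encodes the macrophage marker F4/80, fell by 1.07 on the log2 scale (SE 0.234, adjusted p = 0.0244), a call lost without S. aureus replicates 2, 3 or 4 (up to 0.0672). The repair-associated macrophage list had 2 genes lower and was not called (0.0763). Kit, the stem cell factor receptor of mast cells and melanocytes, rose by 1.2 (SE 0.136, adjusted p = 0.00332), while Mitf, a transcription factor of both cell types, fell by 0.51 (SE 0.0787, adjusted p = 0.00875). The melanocyte list was lower (0.0396; adjusted p = 0.398 with an estimated correlation), with 1 gene lower, 2 list alone, and a call that 9 of the 12 fits with 1 library left out did not make. Those were the fits without vehicle 2, 3 or 4, A. faecalis 1, 2 or 3, or S. aureus 1, 2 or 3 (up to 0.154). The mast cell list was not called (0.369).

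Tissue lists separated as well. The adipocyte list was lower, with 4 of 18 genes called and 15 lower when adjusted over the list alone (median log2 fold change -1.30, camera adjusted p = 4.58e-06, and 0.398 with an estimated correlation); Nrg4, an adipose-secreted neuregulin, fell by 0.92 (SE 0.184, adjusted p = 0.0183; 0.0688 without S. aureus replicate 3). Vehicle replicate 3 had an adipocyte score of 2.12 where the other vehicle libraries had -0.165 to 0.0149. It raised the vehicle mean, so the size of this list's change rests in part on that library, although the list was still called without it. The skeletal muscle list was lower with 2 genes called and 10 list alone (0.000292) and the erythroid list with 4 genes called and 5 list alone (0.000271), with an adjusted p of 0.417 and 0.398 with an estimated correlation. The embryonic myosin gene Myh3, outside that muscle list, fell by 3.48 (SE 0.592, adjusted p = 0.0107), and its log2 fold change was -2.75 without vehicle replicate 3. Endothelial genes rose in 6 of 21 cases, 10 list alone (median 0.399, adjusted p = 1.86e-05, and 0.398 with an estimated correlation). Flt1, a receptor of vascular endothelial growth factor, rose by 0.76 (SE 0.147, adjusted p = 0.0163), a call lost without S. aureus replicates 3 or 4 (up to 0.0599). The hypoxia and glycolysis list was higher with 4 genes called and 5 list alone (9.28e-07), the cell cycle list with 2 and 2 (1.16e-07), the myofibroblast and provisional matrix list with 1 and 7 (0.000303), and the immediate-early list with 5 and 6 (3.54e-05). Each of these 4 had an adjusted p of 0.398 with an estimated correlation. Vegfa rose by 1.04 (SE 0.226, adjusted p = 0.0241), a call lost without S. aureus replicates 2, 3 or 4 (up to 0.0716).

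The growth factor list was higher with 5 genes called, and 7 were higher and 4 lower list alone (adjusted p = 0.0396, and 0.398 with an estimated correlation), but the call was lost without vehicle replicates 1, 2 or 4, A. faecalis replicate 3 or S. aureus replicate 1 (up to 0.133). Fgf7, the keratinocyte growth factor of fibroblasts, rose by a log2 fold change of 0.87 (SE 0.177, adjusted p = 0.0193; 0.0608 without S. aureus replicate 3). The mitochondrially encoded mRNA list was higher with 1 gene called, also 1 list alone (0.0369, and 0.55 with an estimated correlation), a call lost without vehicle replicates 1 or 2 or S. aureus replicates 1 or 3 (up to 0.229). None of the 19 list calls between S. aureus and vehicle held with an estimated correlation. Fry, which asks another question, called 4 lists, those of matrix metalloproteinases, wound-edge keratinocytes, melanocytes and erythroid cells. Lists not called and not yet given were those of T and NK lymphocytes (camera adjusted p = 0.478), dendritic cells (0.145) and Schwann cells (0.637), with no called gene, and of B and plasma cells (2 genes lower; 0.0714), fibroblasts (2 higher, 4 lower; 0.419), pericytes (1 higher, 1 lower; 0.341), pattern recognition (1 higher; 0.219) and complement and coagulation (2 higher, 2 lower; 0.341). Leaving out 1 library gave a call of the basal keratinocyte (vehicle 2 or S. aureus 2; adjusted p from 0.0198), repair-associated macrophage (vehicle 2 or 3; from 0.0173), B and plasma cell (vehicle 3 or S. aureus 1; from 0.016), T and NK lymphocyte (S. aureus 4; 0.0451), dendritic cell (S. aureus 1; 0.0284) and pattern recognition (vehicle 2; 0.04) lists. On the complement list Cd55, which protects cells from complement, fell by 0.81 (SE 0.126, adjusted p = 0.00875), and Thbd, thrombomodulin, rose by 1.0 (SE 0.186, adjusted p = 0.0149; 0.0503 without S. aureus replicate 3).

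The third comparison tested the difference between the bacteria directly. Levels of Mmp10, Mmp13, Mmp12, Mmp3 and Mmp1b were all lower with A. faecalis than with S. aureus. The log2 fold change of Mmp10 was -3.15 (SE 0.171, adjusted p = 6.98e-06 by edgeR; n = 4 per group) and that of Colq was 2.47 (SE 0.174, adjusted p = 6.98e-05). Mmp13 was at 15.4 ± 5.36 CPM with A. faecalis and 115 ± 37.9 CPM with S. aureus (log2 fold change -2.89, adjusted p = 0.00146). Mmp12 and Mmp3 differed by -2.35 (adjusted p = 0.00171) and -2.23 (adjusted p = 0.00154), and the weakly expressed Mmp1b by -1.35 (adjusted p = 0.00432). Those 5 were the metalloproteinases called, and Mmp15 made 6 when adjusted over the list alone; the list was lower by camera (adjusted p = 0.000797; adjusted p = 0.124 with an estimated correlation). EdgeR called 2310 genes, 922 higher and 1388 lower with A. faecalis, of which 218 and 523 differed at least 2-fold. The excess of lower genes was smaller under upper-quartile scaling, with 1124 higher and 1211 lower. The count was 1313 without S. aureus replicate 3, 1510 without S. aureus replicate 4, and 1423, 1337 and 1392 without A. faecalis replicates 2, 3 and 4. The groups did not overlap in 4243 genes, 23.3% of those tested against 2.86% by chance.

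Wound-edge genes were lower with A. faecalis than with S. aureus in 17 of 28 cases, and in 21 when adjusted over the list alone. The median log2 fold change was -1.07 (camera adjusted p = 4.06e-13), and this was the one list of the comparison whose call held with an estimated correlation (adjusted p = 0.0318). Gjb2 differed by -1.89 (SE 0.235, adjusted p = 0.00104), Hbegf by -1.72 (SE 0.163, adjusted p = 0.000592), Tgfa, another receptor ligand, by -1.70 (SE 0.223, adjusted p = 0.00131), and Plaur by -2.16 (SE 0.31, adjusted p = 0.002). The basal keratinocyte list, with 1 gene higher and 1 lower, was not called (0.212). Krt15 was higher with A. faecalis (log2 fold change 3.98, SE 0.608, adjusted p = 0.00257), as were Krt77 and Serpina3b (3.20 for both, adjusted p = 0.00695 and 0.00355). The differentiated epidermis list was lower, with 9 of 31 genes lower and 1 higher, and 12 and 3 list alone (adjusted p = 0.000797; adjusted p = 0.624 with an estimated correlation). Alox12b, a lipoxygenase of the skin barrier, differed by -2.51 (SE 0.317, adjusted p = 0.00104). Sprr2b, one of a family of close paralogs, differed by -6.07 (SE 0.929, adjusted p = 0.00258). The hair follicle list was lower with 4 genes called, also 4 list alone, and the sebaceous gland list was higher with none called; both had a camera adjusted p of 0.0169, and adjusted p of 0.478 and 0.583 with an estimated correlation. The hair follicle call was lost without replicate 1 of either bacterium (up to 0.0694), and the sebaceous gland call without A. faecalis replicate 4 or S. aureus replicate 3 (up to 0.0865).

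Some antimicrobial and inflammatory genes were lower with A. faecalis than with S. aureus. On the IL-17 and antimicrobial list 11 of 26 genes were lower, 15 list alone (median log2 fold change -0.94, adjusted p = 1.84e-06, and 0.478 with an estimated correlation). Scaled by library size, Il17a was 156 times as high with S. aureus as with A. faecalis (251 and 2 counts), with a wide counting interval of 42.8 to 1300 because A. faecalis had so few, both in replicate 1. Without that library no count was left in the group and no ratio could be formed. Defb4 differed by -4.22 (SE 0.479, adjusted p = 0.000795). Cytokine genes were lower in 11 of 32 cases and higher in 1, and 17 and 4 list alone (adjusted p = 0.000145, and 0.524 with an estimated correlation). Osm was at 12.9 ± 3.12 CPM with A. faecalis and 125 ± 36.6 CPM with S. aureus (log2 fold change -3.27, adjusted p = 0.00179). Interferon-stimulated genes were lower in 17 of 36 cases, 25 list alone (median -0.693, adjusted p = 2.77e-11, and 0.478 with an estimated correlation), with Oas3 at -2.10 (SE 0.261, adjusted p = 0.00104). Neutrophil genes were lower in 10 of 25 cases, 12 list alone (median -1.06, adjusted p = 2.19e-05, and 0.534 with an estimated correlation); S100a8 was at 994 ± 418 CPM against 4031 ± 679 CPM (log2 fold change -2.02, adjusted p = 0.0388), a call lost without any 1 of the 8 A. faecalis and S. aureus libraries (up to 0.105), and Ly6g and Retnlg differed by -4.24 and -5.04 (adjusted p = 0.0097 and 0.00928).

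On the monocyte and macrophage list 10 of 19 genes were higher with A. faecalis than with S. aureus; 11 were higher and 1 lower when adjusted over the list alone (median log2 fold change 0.412, camera adjusted p = 0.000114; adjusted p = 0.495 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, was at 829 ± 171 CPM against 422 ± 24.2 CPM (log2 fold change 0.97, adjusted p = 0.00415). Mertk, which serves the uptake of dead cells, differed by 0.75 (SE 0.103, adjusted p = 0.00162) and Marco, a scavenger receptor, by 3.25 (SE 0.714, adjusted p = 0.0133). Tlr9, a sensor of microbial DNA, differed by 1.43 (SE 0.234, adjusted p = 0.00344), and Clec7a, a receptor for fungal glucans, by -1.30 (SE 0.234, adjusted p = 0.00519). The T cell coreceptor Cd4, which macrophages can also carry, differed by 0.97 (SE 0.154, adjusted p = 0.00283). Lyve1 and Cd209f of the repair-associated list were lower by -1.08 and -0.89 (adjusted p = 0.00378 and 0.00273), and that list was not called, with 2 genes higher and 3 lower (0.911).

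Cell cycle genes were lower with A. faecalis than with S. aureus in 10 of 33 cases, 26 list alone (median log2 fold change -0.427, adjusted p = 3.41e-10, and 0.478 with an estimated correlation), with Rrm2 at -0.74 (SE 0.113, adjusted p = 0.00251). Lower lists also were growth factors (10 of 28 genes lower, 10 list alone; 0.000947), myofibroblast and provisional matrix (7 of 23, 11 list alone; 9.93e-05), endothelium (5 of 21, 10 list alone; 0.000103), hypoxia and glycolysis (4 of 27, 7 list alone; 2.07e-05), immediate-early genes (8 of 22, 11 list alone; 7.18e-05) and mast cells (3 of 13, 5 list alone; 0.00169). The adjusted p of these 6, in this order, were 0.191, 0.478, 0.524, 0.524, 0.495 and 0.478 with an estimated correlation. Kit, the receptor of mast cells and melanocytes, differed by -1.21 (SE 0.136, adjusted p = 0.000759). The adipocyte list was higher with 1 of 18 genes called, also 1 list alone (0.000605, and 0.595 with an estimated correlation), and the melanocyte list with 2 of 6, 3 list alone (0.0118 and 0.191). Lists not called and without a called gene were those of inhibitors of metalloproteinases (0.721), skeletal muscle (0.0666), pericytes (0.641), Schwann cells (0.164), erythroid cells (0.126) and mitochondrially encoded mRNA (0.265). Those with called genes were other wound proteases (2 higher, 5 lower; 0.0776), T and NK lymphocytes (3 higher, 1 lower; 0.75) and B and plasma cells (1 higher; 0.577). The same held for dendritic cells (1 higher, 1 lower; 0.3), fibroblasts (3 higher, 1 lower; 0.711), pattern recognition (3 higher, 1 lower; 0.174) and complement and coagulation (4 higher, 4 lower; 0.9). Leaving out 1 library gave a call of the skeletal muscle (vehicle 1, A. faecalis 2 or S. aureus 2; adjusted p from 0.0166), other wound protease (S. aureus 2; 0.0268), basal keratinocyte (S. aureus 4; 0.0178), erythroid (A. faecalis 4; 0.0245) and pattern recognition (A. faecalis 1; 0.0499) lists. Of the 85 called genes that the naming rule took, 68 were called in all 12 fits with 1 library left out. Of the called genes given here with a value for this comparison, S100a8 was the one whose call depended on a single library.

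**Figure D3:**
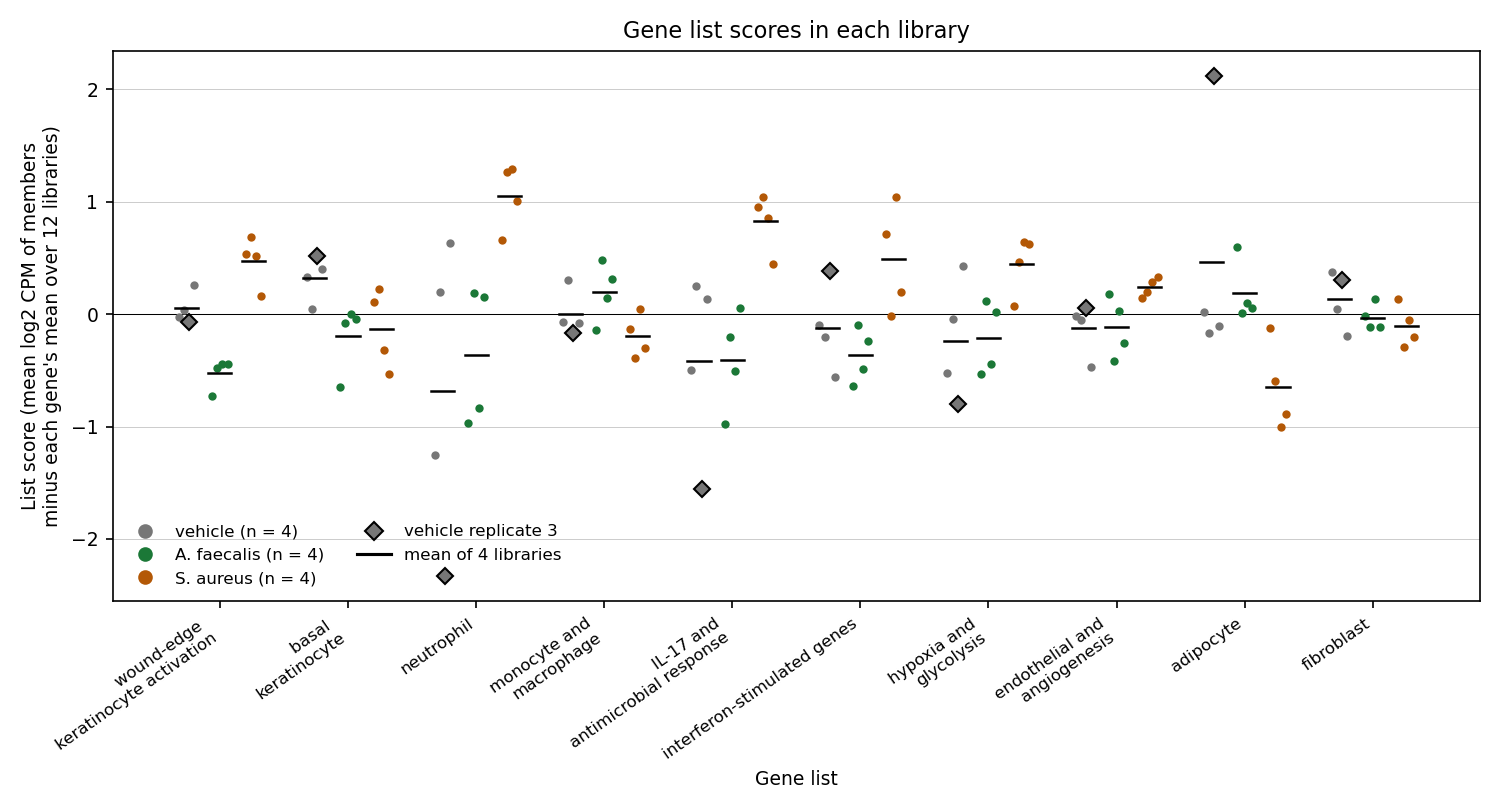
Scores of 10 gene lists in the 12 libraries (mean log2 CPM of the members minus each gene's mean over all libraries), each point 1 library and each bar the mean of 4, with vehicle replicate 3 as a diamond. Vehicle replicate 3 has the highest adipocyte score (2.12) and the lowest neutrophil score (-2.33).

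Both bacteria were compared with the same vehicle libraries, which by itself makes their log2 fold changes agree. No gene was called in the same direction with both by edgeR, while Mmp10 and Colq were called in opposite directions. Colq fell by 0.82 with S. aureus (SE 0.17, adjusted p = 0.0209), a call lost without vehicle replicate 1 or S. aureus replicates 3 or 4 (up to 0.0695). At an unadjusted p under 0.05 in both comparisons, 234 genes went the same way and 256 opposite ways. Simulated unchanged groups, compared with a shared simulated vehicle group, gave a mean of 191 and 2.2. The simulations redrew every library, vehicle included, without the structure of the real samples, so their ranges are only a rough guide. DESeq2 called 13 genes in the same and 35 in opposite directions. Independent lists with these counts of calls would share 0.039 genes higher and 0.03 lower with both. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.226, against a mean of 0.493 in the simulations (0.444 to 0.535). Their covariance, 0.0477, lay within the range of the simulations (mean 0.0546, 0.0458 to 0.0646). With the vehicle group divided so that each bacterium had 2 vehicle libraries of its own, r was -0.25 to 0.0356 over the 6 divisions. Without vehicle replicate 2 the number of genes called in the same direction was 3, and without vehicle replicate 4 it was 4.

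**Figure D4:**
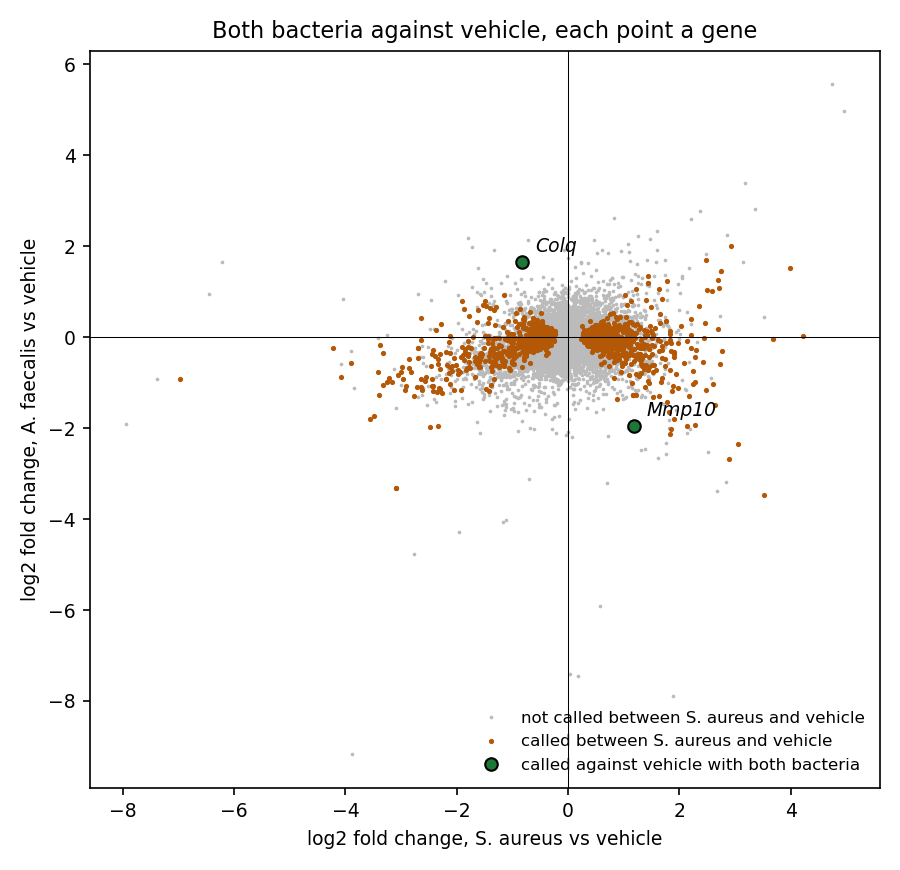
Log2 fold change of each gene against vehicle with A. faecalis (vertical axis) and S. aureus (horizontal axis), with the 1246 genes called for S. aureus in orange. Mmp10 and Colq are the 2 genes called with both bacteria, and they lie in opposite quadrants.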

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

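No test of this part was chosen after its result was seen, except that the difference between the bacteria was singled out for Mmp10 and Colq because both were called against vehicle. Effects of the bacteria went opposite ways for these genes. The log2 fold change against vehicle with A. faecalis minus that with S. aureus was -3.15 for Mmp10 (SE 0.171, adjusted p = 6.98e-06) and 2.47 for Colq (SE 0.174, adjusted p = 6.98e-05), tested directly as the difference between the bacteria by edgeR.

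Library totals, list scores and the levels of the 81 genes named in the text were searched for a library far from the other 3 of its group. Of 348 groups of 4 values, 24 had one (6.9%), where chance gives about 1 in 20 for independent values; genes of one tissue are not independent.

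Vehicle replicate 3 accounted for 7 of the 24. Its adipocyte score was 2.12 (other vehicle libraries -0.165 to 0.0149) and its erythroid score -0.0636 (0.592 to 0.696). Its levels were 235 CPM for Flg2 (64.0 to 87.9), 51.7 CPM for Krt15 (12.9 to 18.2), 141 CPM for Krt77 (34.6 to 51.2), 161 CPM for Timp4 (17.4 to 35.3) and 134 CPM for Gjb2 (161 to 166). The vehicle means of Flg2, Krt15, Krt77 and Timp4 are thus raised by this library, although the first 3 of these genes were called lower with S. aureus in each of the 12 fits with 1 library left out.

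A. faecalis replicate 1 had wound-edge and basal keratinocyte scores of -0.728 (others of its group -0.478 to -0.442) and -0.65 (-0.0785 to 0.00507) and an adipocyte score of 0.592 (0.00595 to 0.0947). It was at 22.9 CPM for Tgm1 (32.4 to 34.2) and 30.5 CPM for Fgf7 (22.4 to 23.6), and at 0.0338 CPM for Il17a, from the 2 counts found in that group. The wound-edge list stayed lower with A. faecalis in each fit with 1 library left out (camera adjusted p at most 1.56e-07). Other vehicle libraries apart were replicate 1 for Colq (3.31 CPM; 2.62 to 2.64), replicate 2 for Marco (76.4 CPM; 6.70 to 17.0) and replicate 4 for Mmp15 (24.2 CPM; 31.4 to 31.7).

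With S. aureus, replicate 1 stood apart for Cd4 (8.83 CPM; 5.72 to 6.17), Cd55 (39.3 CPM; 29.9 to 31.1) and Mmp19 (128 CPM; 144 to 145). Replicate 2 did so for Camp (4.63 CPM; 1.24 to 1.82), Ceacam10 (7.12 CPM; 4.79 to 5.06) and Mertk (51.3 CPM; 60.0 to 60.6). Replicate 3 was at 8.10 CPM for Aldh1a2 (15.2 to 16.3) and replicate 4 at 1.88 CPM for Mmp1b (3.63 to 3.78). No technical or biological explanation was tested for these single values.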

How the results depend on the processing

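The covariate and thinning alternatives were chosen only after the data were seen, and so were the tests on them. With DESeq2 in place of edgeR, 121 genes differed between A. faecalis and vehicle, 2851 between S. aureus and vehicle, 3 matrix metalloproteinase genes changed with A. faecalis, and 13 genes changed in the same direction with both bacteria. DESeq2 was given 24550 genes, all those with any count, and then applied its own filter. EdgeR tested 18218, so the tool and the filter changed together. The cause was not tested. Fitting only the 2 groups compared gave 2, 350 and 3459 genes for the 3 comparisons (A. faecalis against vehicle, S. aureus against vehicle, and between the bacteria). A minimum change of 2-fold left 424 genes for S. aureus against vehicle and 741 between the bacteria, and a threshold of 0.1 gave 2859 and 3650, by construction. With an estimated correlation 1, 0 and 1 of the 34 lists were called in that order, and with fry, which asks another question, 1, 4 and 11. With the basal keratinocyte score as a covariate the total was 1 gene for A. faecalis and 90 for S. aureus. With the adipocyte score it was 467 for S. aureus. The neutrophil score gave 41 genes for A. faecalis, with 2 matrix metalloproteinases. These totals can include genes not called without the covariate, and the cause was not tested.

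Leaving out 1 library at a time gave 2 to 10 genes for A. faecalis, 260 to 1750 for S. aureus and 1313 to 3457 between the bacteria. The count of matrix metalloproteinases with A. faecalis was 1 in each of these fits, that of genes shared in direction was 0 to 4, and those of lists were 12 to 20, 17 to 20 and 18 to 21. Without vehicle replicate 1 the cell cycle list reversed with A. faecalis (adjusted p = 0.593; 1.62e-05 to 0.593 over these fits). Without vehicle replicate 3 the adipocyte (0.00742; over these fits 0.00375 to 0.261), neutrophil (0.28; 3.5e-05 to 0.402), cytokine (0.0191; up to 0.842) and hypoxia (0.0394; 0.00547 to 0.809) lists reversed in that comparison, the first and the last 2 of them being called in the new direction. With the neutrophil score as a covariate the log2 fold changes of Mmp8 (0.88), Mmp9 (0.65) and Mmp25 (0.54) between the bacteria reversed, where Mmp8 and Mmp9 are themselves on the neutrophil list and none of the 3 was called without the covariate.

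DESeq2 size factors gave 2, 1263 and 2271 genes for the 3 comparisons, upper-quartile scaling 2, 1298 and 2335, no filter 2, 941 and 1929, a minimum of 1 CPM 2, 1295 and 2278, and thinned libraries 2, 1233 and 2245. With the replicate number as a block the counts were 2, 1038 and 2120. The block ended the call of the matrix metalloproteinase list and gave one of the complement list for A. faecalis, and for S. aureus it ended the calls of the melanocyte list and of 13 named genes, Mmp28 and Timp4 among them. Between the bacteria it ended those of 3 named genes and no list. Whether the numbers pair the samples cannot be decided from the values. For this, the mean of its own group was subtracted from the log2 CPM of each library. Libraries with the same number then correlated across genes at 0.07 to 0.182 for A. faecalis and vehicle. The values were -0.21 to 0.0797 for S. aureus and vehicle, and -0.14 to 0.0244 between the bacteria. The best match was the library of the same number in 2, 0 and 0 of 4 cases. A. faecalis replicates 1 and 3 both matched vehicle replicate 3 best, and replicates 2 and 4 both matched vehicle replicate 4. Over the named genes and all alternatives, 4793 results counted as unchanged, 612 lost a call and 23 gained one. Another 67 uncalled values moved by more than their SE, and 3 results reversed. For lists the counts were 1541, 139, 49, 0 and 5. Direction was checked only where the main or the alternative fit made a call. Results uncalled in both fits may thus have changed sign and still count as unchanged. With 4 libraries per group, changes of 1.5-fold were mostly missed on simulated data (23.9% recovered), which limits what the A. faecalis comparison could detect.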

Other observations

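The gene families and the test of the Mmp10 to Mmp3 ratio were chosen only after the values were seen, and so were the tests on vehicle replicate 3 and the test of neutrophil content for S. aureus against vehicle. All 6 late cornified envelope genes of the Lce3 family were lower with A. faecalis than with S. aureus under each of 3 scalings (median log2 fold change -2.99), in each of the 12 fits with 1 library left out. Lce3a was at 0.976 ± 0.506 CPM with A. faecalis, 3.36 ± 0.816 CPM with vehicle and 12.6 ± 4.49 CPM with S. aureus (mean ± SD, n = 4; log2 fold change between the bacteria -3.72, adjusted p = 0.000713 by edgeR). Of the 12 Sprr2 genes 9 were lower with A. faecalis (median -2.09), and 5 without A. faecalis replicates 2 or 3 or S. aureus replicate 1. Of the 14 Lce1 genes none was called between the bacteria under any of the scalings. Close paralogs share reads in these families.

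Histone genes of the Hist1h cluster, transcribed in S phase, were lower with A. faecalis than with S. aureus in 43 of 50 cases (41 with upper-quartile scaling, 32 to 44 with 1 library left out). Hist1h1e rose with S. aureus by a log2 fold change of 1.17 (SE 0.149, adjusted p = 0.00648). Skint genes, expressed in epidermis and thymus, fell with S. aureus against vehicle in 6 of 9 cases (5 with DESeq2 size factors or upper-quartile scaling). Without vehicle replicate 1 or S. aureus replicate 3 that count was 4, and without S. aureus replicate 4 it was 3. Skint1 fell by 2.02 (SE 0.278, adjusted p = 0.00648).

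Mmp10 and the wound-edge list were lower with A. faecalis than with vehicle, and a lower share of keratinocytes in those samples was weighed. With the basal keratinocyte score as a covariate the log2 fold change of Mmp10 was -1.83 (SE 0.206, adjusted p = 0.0448), against -1.96 without it, and over the other alternatives it was -2.09 to -1.83. Colq lost its call with this covariate (adjusted p = 0.123) at the same log2 fold change, 1.65, because its SE rose to 0.222 from 0.166, and it was called under the other alternatives (1.56 to 1.76). The 26 wound-edge genes outside the other keratinocyte lists had a median of -0.337 with the covariate and -0.563 without it. With the covariate 23 of the 26 were lower. The score is an imprecise measure of keratinocyte share. Within A. faecalis it varied mostly through replicate 1 (-0.65, the others -0.0785 to 0.00507). The covariate fits thus cannot exclude a keratinocyte share as the explanation of Mmp10 or of the list. Reads shared with the paralog Mmp3 would move both genes together, whereas the log2 ratio of Mmp10 to Mmp3 differed by -1.58 and its highest A. faecalis value (-5.76) lay below the lowest vehicle value (-5.14). A lower activation of wound-edge keratinocytes with A. faecalis remains a hypothesis, found and tested on the same libraries.

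Vehicle replicate 3 stood apart in adipocyte (2.12) and neutrophil (-2.33) scores. Adipose tissue that only diluted the other cell types would lower its fibroblast score, which was 0.307, above the lowest of the other vehicle libraries (-0.192). Stroma of adipose tissue may express the same genes, so the fibroblast score cannot exclude more fat in the sample. Vehicle replicate 3 was also the highest of the 12 libraries in sebaceous gland (1.04), Schwann cell (0.739), skeletal muscle (0.622) and pericyte (0.578) scores. It was the lowest in cytokine (-1.47) and IL-17 (-1.56) scores. Its depth was 62.4 M (mega) estimated counts, so a shallow library is no explanation. Its Mmp10 level of 9.94 CPM lay among the other vehicle libraries (6.45 to 10.7) and outside the A. faecalis (2.25 to 2.60) and S. aureus (17.6 to 24.8) libraries. That argues against a library of another group, but rests on a single gene picked with this library counted as vehicle. Different tissue content of the sample and a sample from outside the series stay open. The calls of Mmp10 and Colq held without this library.

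Many genes differed between S. aureus and the other groups, and few between A. faecalis and vehicle. Vehicle replicate 3 hiding differences was weighed, but without it 3 genes differed between A. faecalis and vehicle. That fit bears on this library alone. Without vehicle replicate 2 the count was 10, and with the neutrophil score as a covariate it rose too, as given above. A split of these libraries across the groups, given below, called 591 genes. Other structure within the groups thus cannot be excluded as a reason for the few calls. With the neutrophil score as a covariate, 68.9% of the genes called between the bacteria were still called in the same direction. The score is an imprecise measure of neutrophil content. It did not overlap between the bacteria (at most 0.188 with A. faecalis, at least 0.658 with S. aureus), so that content stays open as the explanation. On libraries thinned to the shallowest, 92.4% of the genes called between the bacteria were still called in the same direction, which leaves little to depth. Between S. aureus and vehicle 28.8% of the called genes were still called with the neutrophil score, where under 5% was set as a fit and over 50% as against it. That fit called 1253 genes, most of them others. The score differs between S. aureus and vehicle too, so for that comparison neutrophil content also stays open as the explanation. Of the 79 called genes that the naming rule took, 49 lost their call with this score. With the basal keratinocyte score 73 lost it and with the adipocyte score 53, so other differences in cell content stay open as well. The pattern was first written for all groups, and it was narrowed to the comparison each test used after these values were seen. A broader response to S. aureus remains a hypothesis.

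The 8 libraries of each comparison were split into 4 and 4 in all 35 ways. The real split gave the most genes for S. aureus against vehicle (1246, highest other 2). The same held for A. faecalis against S. aureus (2310, highest other 2). The share of 0.0286 is the smallest that 35 splits can give. Other splits mix the groups, which widens the spread and lowers their counts. The calls thus followed the group labels, but the splits cannot exclude chance or a batch that coincides with the groups. For A. faecalis against vehicle 3 of the 35 splits gave at least the real 2 genes, so for that count chance cannot be excluded. The highest other split called 591 genes and set vehicle 1, vehicle 3, A. faecalis 1 and A. faecalis 3 against the rest. It points to a structure of the samples that the groups do not explain, and those 4 libraries had the lowest neutrophil scores of the 8 (-1.25, -2.33, -0.971 and -0.836, the others 0.151 to 0.631). The split also sets replicates 1 and 3 of both groups against replicates 2 and 4. Whether shared numbers mark a pairing could not be decided from the values.

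Whether the bacteria move genes in opposite directions from vehicle was tested as a hypothesis. Of the 1246 genes called between S. aureus and vehicle, 49.8% had the opposite sign with A. faecalis. When the vehicle libraries were divided between the bacteria, 63.6% to 79.4% did. Each division called its own set of 77 to 3635 genes, so these shares are not over the same genes. Over all genes the share was 41.9%, against a mean of 33.5% in simulated unchanged groups (32.9% to 34.1%). A change with S. aureus unrelated to that with A. faecalis would raise it too. The shared vehicle libraries pull the values over undivided groups down and each division leaves 2 vehicle libraries per comparison, so the question stays open.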
